A study of Mus musculus with 4 samples.

How the data were processed

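RNA from mouse splenocytes was measured on 4 Illumina bead arrays. Each array held biotin-labelled RNA from a pool of 3 mice, per the labels, so each combination of 2 genotypes and 2 treatments had 1 array and no replicate. The main table was the deposited one that had not been normalized. It gave, per the file headers, the mean bead signal intensity of each of 25697 probes, the standard error of that intensity over the beads, the number of beads and a detection p-value. The intensities came from GenomeStudio 2011.1, per the submitters' processing notes. They were linear and not background-subtracted, as the smallest value on every array was over 100. The detection p-value deposited for each probe and array moved in steps of 1 in 798, as a rank among negative-control beads would. A second deposited table held log2 values with 1 row per gene symbol. RMA is named in the submitters' processing notes without its role. How probes were combined into these log2 values was not stated by the authors. The column medians of that table were 3.74 for wild type untreated, 3.74 for heterozygous untreated, 3.73 for wild type with prednisolone and 3.74 for heterozygous with prednisolone. Its differences between arrays followed those of the bead signals, with r of 0.857 to 0.926 across genes of high bead signal for each array's own column. The r was at most 0.022 for the other columns, where centring each gene over the 4 arrays itself lowers it. The r of the own columns settled the direction of the table. Its centring and exact scale stayed unknown, and it served as an alternative only.

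Signals were background-corrected with a normexp model fitted from the detection p-values (offset 16), quantile normalized and set on a log2 scale with neqc of limma 3.58.1 in R 4.3.3. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. A gene took the value of its probe with the highest mean log2 signal over the 4 arrays. Of the probes, 23788 received a current symbol through their Entrez identifier in a RefSeq gene table, which changed the symbol of 3935, and 1909 kept the symbol of the file. The probes represented 18113 genes, 4966 of them with several probes. A gene was called detected where its detection p-value was below 0.01, and 6634 genes were detected on all 4 arrays. Counts, tests and named genes refer to these unless stated otherwise. Probe coordinates are those of the deposited table, whose genome build was not given.

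The median number of beads per probe was 30 for wild type untreated, 31 for heterozygous untreated, 34 for wild type with prednisolone and 34 for heterozygous with prednisolone. The median bead error of detected probes was 4.62%, 4.48%, 4.23% and 4.31% of the signal, in that order. Bead errors are technical. They leave out the differences between pools, cultures and arrays, so they understate the error of every difference given here, and the number of arrays limits the precision.

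The choices that follow were made before the data were examined. Prednisolone was compared with no treatment within each genotype, and heterozygous with wild-type cells within each treatment. Genes were counted where both such differences passed 2-fold (prednisolone) or 1.5-fold (genotype) in the same direction. These counts are values without a test. As a secondary analysis, an additive limma model of genotype and treatment was fitted with lmFit and eBayes (two-sided, Benjamini-Hochberg adjusted p below 0.05). Its 1 residual degree of freedom per gene is the genotype by treatment difference, so each genotype stood in for a replicate of the treatment and each treatment for a replicate of the genotype. The words rose and fell are kept for genes called by this model, over all genes or, where stated, over a list alone. The difference between the responses of the 2 genotypes had no residual degree of freedom and could not be tested per gene. It was summarised over genes whose mean response passed 2-fold, as a median with its 95% confidence interval over genes, which are not independent replicates.

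Gene lists and cell type markers were fixed at the same stage, 18 in all. The median of each list with at least 5 detected members was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, with limits of 2.5 and 97.5. For 6 of the 18 lists fewer members were detected: those of T cells, natural killer and cytotoxic cells, monocytes and macrophages, neutrophils, dendritic cells and erythroid cells. Members were also called with p adjusted over the list alone, with no adjustment across lists. Of all 6634 genes, 1384 for prednisolone and 1237 for genotype had an unadjusted p below 0.05 in limma. Calls over a list alone can therefore be frequent in any list. Named genes were Ikzf1 and Nr3c1, up to 10 highest and 10 lowest by mean response among genes past 2-fold in both genotypes (only 2 were lower), up to 8 highest and 8 lowest by mean genotype difference among those past 1.5-fold in both treatments, genes among the 8 most positive and 8 most negative response differences, and up to 6 members of each list, with every glucocorticoid receptor target allowed. For genes detected on both arrays of one condition and on neither of the other, a bound was computed and up to 5 per direction were named. It is the mean log2 signal of the bright arrays minus the mean, over the dim arrays, of the higher of the gene's own signal and the lowest signal of any detected probe. The bounds have no error, and many of these genes lay near the lowest detected signals of 5.74 to 5.83. How many genes would show such a pattern of detection without an effect was not determined.

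The alternatives were an offset of 50, median scaling, no background correction, the submitters' log2 values, detection on at least 1 array, no filter, the mean of all probes of a gene, other size thresholds, a false discovery rate of 0.1, a prior variance with an intensity trend, and other ways to choose responding genes. On simulated data with the 6634 genes, the additive model for prednisolone recovered 61% of 100 genes changed 4-fold and 0% of 100 changed 2-fold, with 0 false calls. The noise of each simulated gene was scaled by a single observed response difference, shuffled over genes, and no genotype effect was simulated. These percentages may therefore not hold for the real fit, which called Irs2 for genotype at -1.09. The simulated noise was independent between genes and arrays. It left out deviations shared by the genes of a pool or culture, so the 0 false calls do not cover these. Of 100 simulated lists of 20 members, 4 without a shift and 100 with a shift of 0.4 fell outside the limits. Their members were drawn at random, so genes that vary together were not simulated. Smaller shifts and shorter lists were not simulated either, so how often these would be found is unknown. No array was left out.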

Results

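Gene expression was measured in cultured splenocytes, the mixed immune cells of the spleen, from C57BL/6J mice that were wild type or heterozygous for a targeted allele of Ikzf1. Ikzf1 encodes IKAROS, a zinc finger transcription factor of lymphocyte development. The cells were cultured with 5 µg/mL lipopolysaccharide (LPS), a bacterial product that activates B cells and macrophages. They were left untreated or received the synthetic glucocorticoid prednisolone for 16 h, at a concentration that the labels do not give. The series title places the experiment in work on IKZF1 and resistance to glucocorticoid therapy in leukemia. The questions addressed were how prednisolone changed expression, how the genotypes differed, and whether the response differed by genotype. There were 4 groups with 1 array each, and each array held RNA pooled from 3 mice. Median signal was 155 in wild type untreated, 160 in heterozygous untreated, 157 in wild type with prednisolone and 161 in heterozygous with prednisolone. The arrays detected 9446, 9611, 9644 and 9415 of 25697 probes in that order, or 36.6% to 37.5%. With 1 array per group no difference has a replicate error, and errors given as bead SE cover technical noise within an array only.

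Ikzf1 itself was lower in the heterozygous cells in both treatments. Its log2 signal was 10.32 in wild type and 9.80 in heterozygous cells without treatment, and 10.38 and 9.81 with prednisolone. The heterozygous cells were thus 30.2% lower untreated and 32.9% lower with prednisolone (mean log2 difference -0.55, bead SE 0.06). The additive limma model did not call this difference (adjusted p = 0.091). The probe lies on chromosome 11 at 11672785 to 11672834 in the coordinates of the deposited table, whose build was not given. The labels do not say which part of the gene the targeted allele alters, so the probe may or may not lie within it. A second Ikzf1 probe, at 11648399 to 11648448, was near background. It was not detected in heterozygous untreated cells, and its difference with prednisolone was 0.19. Nr3c1, which encodes the glucocorticoid receptor, was not above background on any array, so its level could not be compared.

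Prednisolone raised a small set of genes known as glucocorticoid targets in both genotypes. Tsc22d3, which encodes the anti-inflammatory leucine zipper protein GILZ, rose by a mean log2 of 1.90 (2.10 in wild type, 1.70 in heterozygous cells, bead SE of the mean 0.08, adjusted p = 0.0308 in limma). Sesn1, a stress-induced inhibitor of mTORC1 signalling, rose by 1.91, and Irs2, an adaptor of insulin receptor signalling, rose by 1.32. The acute-phase gene Saa3 had the highest mean response, 2.16. Cd8b1, a chain of the co-receptor of cytotoxic T cells, fell by 1.84, to signals of 5.81 and 5.93 near the lowest detected ones. Its value was -1.06 with the mean of all probes and -0.86 without background correction.

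Across all genes, 15 differed at least 2-fold in the same direction in both genotypes, 13 higher and 2 lower with prednisolone, and 0 did so in opposite directions. In wild-type cells 51 genes passed 2-fold (35 higher, 16 lower), and in heterozygous cells 28 did (21 higher, 7 lower), both counts including these 15. The standard deviation of the response over all genes was 0.31 in wild-type and 0.27 in heterozygous cells. The 2 counts therefore do not by themselves show a weaker response. The additive limma model called 10 genes, 8 that rose and 2 that fell, with 1384 genes at an unadjusted p below 0.05. Besides those above, Cyp4f18, a cytochrome P450 that hydroxylates leukotrienes, rose by 1.86, and Hs3st1, a heparan sulfate sulfotransferase, by 1.67. The unplaced entry LOC100044439 rose by 1.70. The deposited table describes it as similar to Cyp4f18, and signal could be shared between such near-identical sequences, so these are uncertain as separate genes. Of the named genes, Ctla4, an inhibitory receptor of T cells, was 1.42 higher, Lgals3bp, a galectin-binding glycoprotein, 1.36 and Id2, an inhibitor of helix-loop-helix transcription factors, 1.34, and the model called none of these 3. The second gene that fell was LOC100048346, by 1.20, which the deposited table describes as similar to Usp18. Without background correction Irs2 was at 0.77 and LOC100048346 at -0.65, and with the mean of all probes Id2 was at 0.87. Across genes the responses of the genotypes correlated with r = 0.515 (Spearman 0.469), where genes are not independent replicates. The model's count depends strongly on the settings, from 0 genes with the submitters' values to 1014 with an intensity trend in the prior. Median scaling gave 12 higher and 4 lower at 2-fold, and 52 risen and 49 fallen genes in the model.

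**Figure D1:**
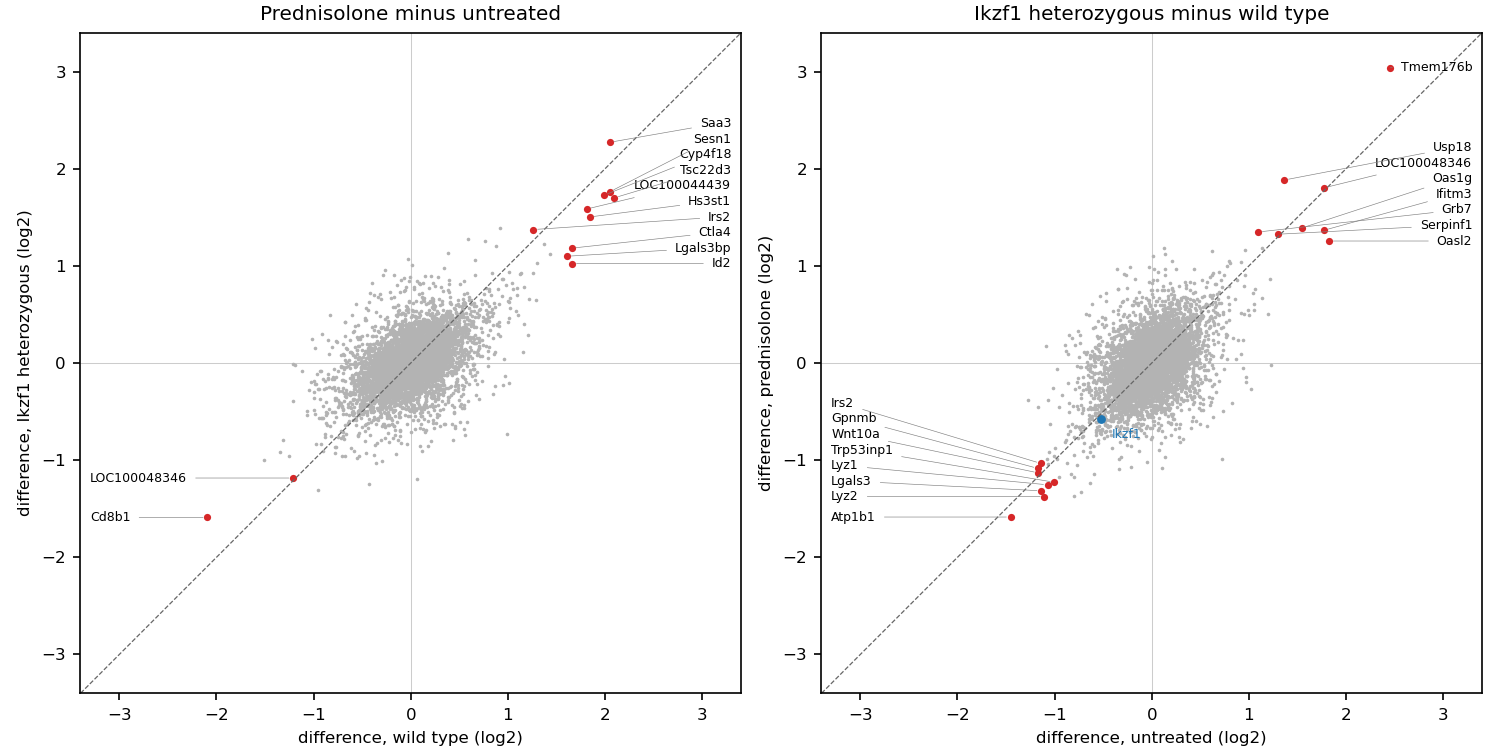
Left, log2 difference of prednisolone minus untreated in wild-type (x axis) against heterozygous cells (y axis). Right, log2 difference of heterozygous minus wild-type cells untreated (x axis) against with prednisolone (y axis). Each grey point is 1 of 6634 genes detected on all 4 arrays, red points are the named genes, the blue point is Ikzf1, and the dashed line marks equal differences; r across genes was 0.515 on the left and 0.487 on the right.

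Glucocorticoid receptor targets were higher as a group. Of 28 such genes on the array 18 were detected, and 14 of these were higher in both genotypes and 2 lower in both. Their median response was 0.44, at percentile 100 of the random lists (0.27, percentile 100, with no filter). The model called 3 as risen over all genes (Tsc22d3, Sesn1 and Irs2), and 12 as risen and 1 as fallen when adjusted over the list alone. Ddit4, an mTORC1 inhibitor, was 1.16 higher, Fkbp5, a co-chaperone of the receptor, 1.02, Dusp1, a MAP kinase phosphatase, 0.82, and Bmf, a pro-apoptotic BH3-only gene, 0.78. Per1 was near 0, at -0.02, and Angptl4 was at -0.45. Pik3ip1, an inhibitor of PI3 kinase signalling in the same list, was detected only with prednisolone, at least 4.23-fold higher. It led 63 genes detected on both prednisolone arrays and neither untreated one, among which the peroxisomal gene Pex11a was at least 2.91-fold higher, haptoglobin (Hp) 2.55-fold, the chitinase-like Chil3 1.92-fold and Olfml3 1.77-fold.

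Inflammatory and metabolic lists were lower with prednisolone. For inflammatory and NF-kB target genes the median response was -0.24 (percentile 0.05), with 9 of 16 detected members lower in both genotypes and 2 higher in both. It was -0.11 (percentile 1.78) with no filter and -0.15 (percentile 0.09) without background correction. The chemokine genes Ccl3, Ccl4 and Ccl5 were at -0.82, -0.70 and -0.73, and the cytokine genes Il6, Tnf and Lta at -0.74, -0.51 and -0.69. None of the 16 was called over all genes, and 6 fell when adjusted over the list alone. Interferon-stimulated genes had a median of -0.23 (percentile 0.02), or -0.42 with detection on at least 1 array. It was -0.32 in heterozygous cells (percentile 0) and -0.15 in wild-type cells (percentile 3.86, inside the limits). Of 14 members 9 were lower in both genotypes and 4 higher in both. Usp18, which removes the ubiquitin-like protein ISG15 from its targets, was at -1.25, Ifit2 at -0.76, Oasl1 at -0.75 and Gbp2, a GTPase, at 0.78. Over the list alone 6 fell and 1 rose, and none was called over all genes. Cholesterol synthesis genes had a median of -0.43 (percentile 0), and 11 of 13 were lower in both genotypes, such as Lss at -0.75, Idi1 at -0.72 and Dhcr7 at -0.61. None was called over all genes and 11 fell over the list alone. Glycolysis genes had a median of -0.27 (percentile 0), with 12 of 13 lower in both genotypes, such as Pfkp at -0.39 and Tpi1 at -0.37, and no member called either way. Heat shock and immediate-early genes had a median of -0.22 (percentile 0.89), with 1 member risen and 3 fallen over the list alone. With detection on at least 1 array it was -0.06, at percentile 25, inside the limits. It also lay inside with no filter (-0.01, percentile 44.2) and without background correction (-0.11, percentile 3.57). Within each genotype it also lay inside them, at -0.04 in wild type (percentile 36.6) and -0.18 in heterozygous cells (percentile 2.68).

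The list of antibody-secreting cell genes was higher as a group. Its members Sdc1 and Tnfrsf17 were not detected, and Prdm1, Jchain and Ell2 were detected on 3 arrays, so none of these was used. Many of the members used serve protein folding in the endoplasmic reticulum, so the median does not by itself show a change in antibody secretion. Antibody-secreting cell genes had a median of 0.29 (percentile 100), and 10 of 13 were higher in both genotypes. Pdia4, an endoplasmic reticulum folding enzyme, was at 0.67, Herpud1 at 0.42 and Xbp1, a transcription factor of plasma cells, at 0.41. The list alone gave 1 risen gene and the test over all genes gave 0. B-cell markers had a median of 0.20 (percentile 99.8) with no call (0.14, percentile 97.1, with no filter). Within each genotype they lay inside the limits, at 0.11 in wild type (percentile 92.6) and 0.12 in heterozygous cells (percentile 97.4). B-lineage regulators were at 0.12 (percentile 95.3), within the limits, but outside with the submitters' values (0.20, percentile 99.6). Of these regulators, Vpreb3, part of the pre-B receptor machinery, was at 0.90 and the repressor gene Bcl6 at -0.76. Cell cycle and DNA replication genes were at 0.02 (percentile 72.1) with no call among 23. Pro-apoptotic genes were at 0.09 (percentile 91.9), with 1 risen and 2 fallen over the list alone. Their median was 0.18 in heterozygous cells (percentile 99.3, outside the limits) and 0.14 in wild-type cells (percentile 95.4). Anti-apoptotic genes were at 0.01 (percentile 57) with no call.

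Several T-cell markers were lower with prednisolone, although too few were detected for a percentile. Of 12 on the array, only Cd8b1 and Lck (-0.43), a kinase of the T-cell receptor, were detected on all arrays. Both fell when adjusted over the list alone, an adjustment that is slight for so few genes. Thy1, a surface glycoprotein of T cells, was at least 2.20-fold lower, Cd3d, a chain of the T-cell receptor complex, at least 2.01-fold and Cd3g at least 1.42-fold, each detected on both untreated arrays and neither prednisolone array. Ctla4, also a T-cell gene but outside this list, was 1.42 higher. Genes with this pattern of detection numbered 61, including Hbb-bh1, at least 1.72-fold lower, the interferon-stimulated Rsad2, 1.68-fold, and Zfp687, 1.60-fold. Of natural killer markers only Prf1 was detected throughout (0.27), of neutrophil markers S100a8 (0.23), of dendritic cell markers Siglech (0.22) and Ccr7 (0.20), and of erythroid markers Car2 (-0.21). Of macrophage markers, Lyz2 was at 0.04, Cd68 at 0.19 and Ctss at -0.29.

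**Figure D2:**
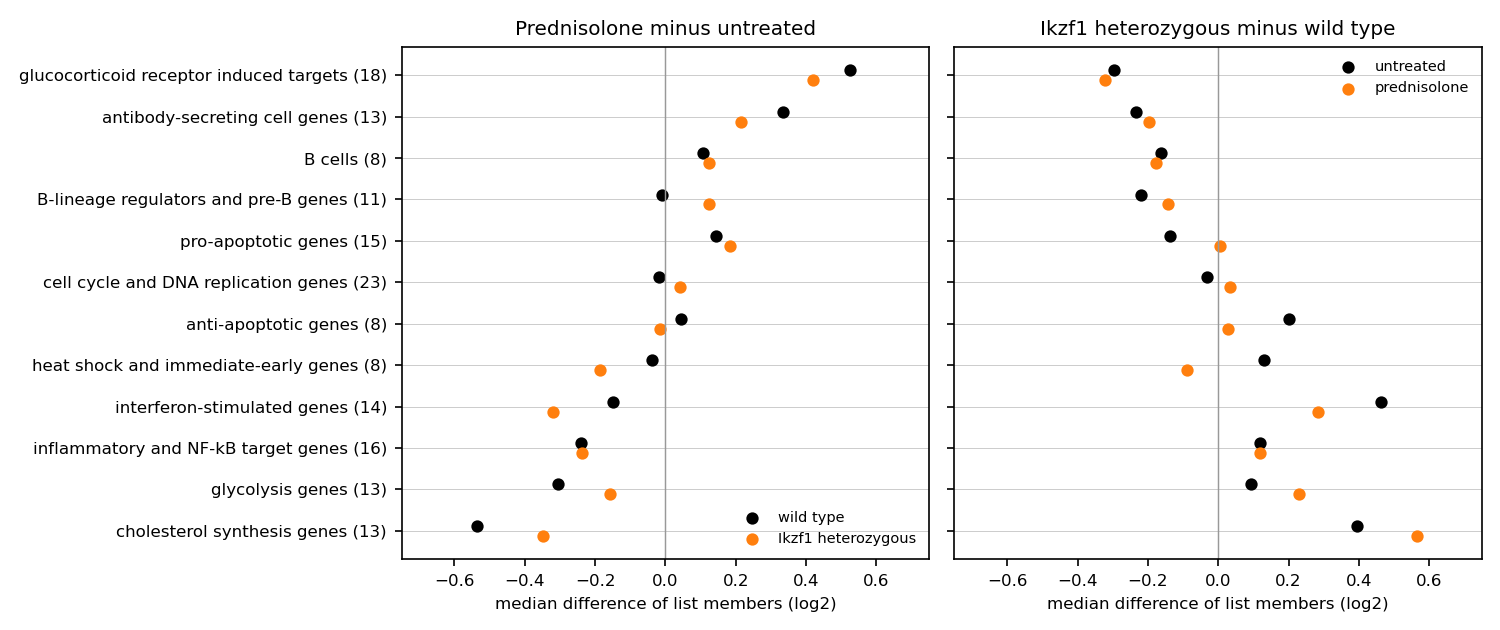
Median log2 difference (x axis) of the detected members of each gene list (y axis, number of members in parentheses), for prednisolone minus untreated in each genotype on the left and heterozygous minus wild type in each treatment on the right. Of the 12 lists shown, those with at least 5 detected members, the glucocorticoid receptor targets had the highest median response, 0.52 in wild-type and 0.42 in heterozygous cells, and the cholesterol synthesis genes the lowest.

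As lists, interferon-stimulated and cholesterol synthesis genes were higher and glucocorticoid receptor targets lower in heterozygous than in wild-type cells, with and without prednisolone. Tmem176b, which encodes a membrane protein of antigen-presenting cells, rose most, with a mean log2 difference of 2.75 (2.46 untreated, 3.04 with prednisolone, bead SE 0.13, adjusted p = 0.0365 in limma). Usp18 was higher by 1.63, and the interferon-induced Ifitm3, Oasl2 and Oas1g by 1.57, 1.54 and 1.47. On the lower side, Atp1b1, a subunit of the sodium pump, fell by 1.52, the lysozyme genes Lyz2 and Lyz1 by 1.24 and 1.16, and Lgals3, which encodes galectin 3, by 1.23.

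In both treatments 105 genes differed at least 1.5-fold in the same direction, 49 higher and 56 lower in heterozygous cells, and 2 differed in opposite directions. At 2-fold the count was 18, 9 in each direction. The additive limma model called 28 genes, 12 that rose and 16 that fell, with 1237 genes at an unadjusted p below 0.05, and it called all 16 of the named genes. Further named genes that rose were Serpinf1 (1.31), which encodes an antiangiogenic serpin, the adaptor gene Grb7 (1.22) and LOC100048346 (1.79). This last entry is uncertain as a gene separate from Usp18, and Lyz1 and Lyz2 may share signal in the same way. Further genes that fell were Wnt10a (-1.15), Gpnmb (-1.13), a glycoprotein of macrophages, the p53 target Trp53inp1 (-1.11) and Irs2 (-1.09). Without background correction the differences were 1.83 for Tmem176b, 1.08 for Usp18, 0.98 for LOC100048346, 0.86 for Oasl2, 0.93 for Oas1g, 0.75 for Grb7, -0.63 for Irs2 and -0.80 for Atp1b1. With the mean of all probes they were 0.75 for Oasl2, 0.88 for Oas1g, -0.57 for Gpnmb and -0.35 for Lyz1, and with the submitters' values 0.84 for Oasl2 and -0.67 for Gpnmb. Second probes detected on all arrays gave -1.31 for Lyz2 and -1.19 for Trp53inp1. The differences in the 2 treatments correlated with r = 0.487 across genes (Spearman 0.427). The labels do not say whether both treatments of a genotype used the same mice. Agreement between treatments may therefore repeat a difference between pools, which the error of the model leaves out. The model's count ranged from 0 with the submitters' values to 774 with an intensity trend in the prior.

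Interferon-stimulated genes had a median genotype difference of 0.33 (percentile 100), or 0.54 with the submitters' values. Of 14 members 11 were higher in heterozygous cells in both treatments and 3 were lower in both. The model called Usp18 and Oasl2 over all genes and 8 members over the list alone, all risen. Isg15, a ubiquitin-like modifier, was at 0.70, Oasl1 at 0.68 and the GTPase genes Igtp and Ifi47 at 0.62 and 0.59. Cholesterol synthesis genes had a median of 0.45 (percentile 100). Of 13 members 12 were higher in both treatments, such as Nsdhl at 0.70, Lss at 0.58 and Msmo1 at 0.53, with 0 called over all genes and 10 risen over the list alone. Glycolysis genes were at 0.14 (percentile 99.6) with no call. They lay inside the limits untreated (percentile 95.8), with the submitters' values (0.11, percentile 96.7) and with the mean of all probes (0.10, percentile 97.1). Inflammatory genes were at 0.10 (percentile 94.5), within the limits, but outside with no filter (0.14, percentile 99.9), with 3 risen and 2 fallen over the list alone. Il2ra, the alpha chain of the interleukin-2 receptor, fell by 0.95, and Ltb was at -0.84.

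**Figure D3:**
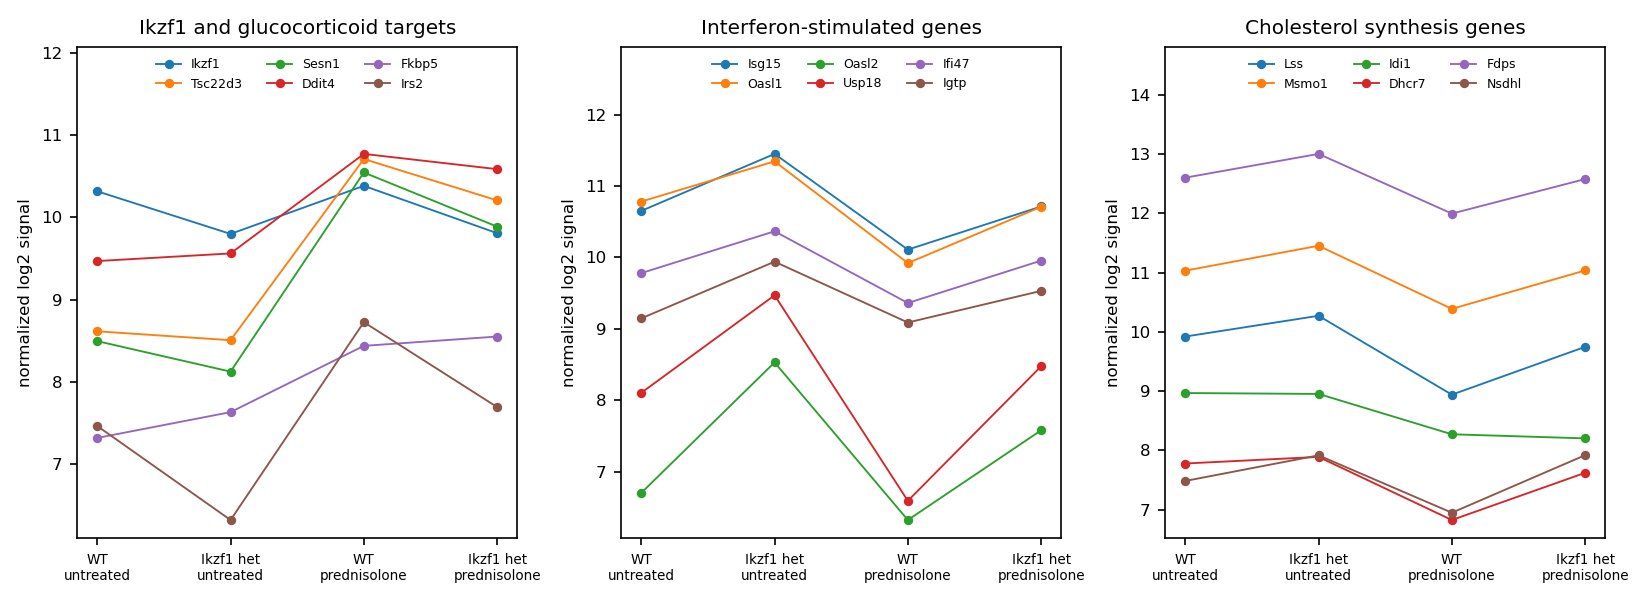
Normalized log2 signal (y axis) on each of the 4 arrays (x axis) for Ikzf1 with glucocorticoid targets, for interferon-stimulated genes and for cholesterol synthesis genes; each point is 1 array and lines join the points of a gene. Tsc22d3 and Sesn1 were higher on both prednisolone arrays, and Usp18 and Oasl2 were higher in heterozygous cells in both treatments.

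Glucocorticoid receptor targets were lower in the heterozygous cells, with a median genotype difference of -0.34 (percentile 0), or -0.22 with no filter. The median was -0.30 already without prednisolone and -0.32 with it. Of 18 members 12 were lower in both treatments and 4 higher in both. Irs2 was the 1 called over all genes, and 9 fell over the list alone. Sgk1, a kinase of ion transport and survival, was at -0.78, Il7r, the interleukin-7 receptor, at -0.72, Dusp1 at -0.67, Zfp36, which destabilises cytokine mRNA, at -0.56 and Sesn1 at -0.52. Antibody-secreting cell genes had a median of -0.24 (percentile 0) with 12 of 13 lower in both treatments, and Dnajb9 was at -0.57. Here 0 were called over all genes and 1 fell over the list alone. B-lineage regulators were at -0.19 (percentile 0.5), such as Foxo1 at -0.51, with 2 fallen over the list alone. They were outside the limits untreated (-0.22, percentile 0.405) and inside with prednisolone (-0.14, percentile 4.68). B-cell markers were at -0.19 (percentile 0.25), or -0.12 with median scaling (percentile 0.37), where Fcrla was at -0.73 and Ly6d at -0.62 but Fcer2a at 0.35, with 2 fallen and 1 risen over the list alone. Heat shock and immediate-early genes were at 0.04 (percentile 68.1), although Egr1, an immediate-early transcription factor, fell by 1.03. Cell cycle genes were at 0.00 (percentile 45.5), pro-apoptotic genes at -0.05 (percentile 26.8, 3 risen over the list alone) and anti-apoptotic genes at 0.04 (percentile 67.9). The anti-apoptotic median was 0.20 untreated (percentile 99, outside the limits) and 0.03 with prednisolone (percentile 60.5).

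Markers of myeloid cells moved with the genotype. Macrophage markers detected on all arrays were all lower in heterozygous cells, Lyz2 at -1.24, Cd68, a lysosomal glycoprotein, at -0.62 and Ctss at -0.40. All 3 fell when adjusted over the list alone, an adjustment that is slight for so few genes. S100a8, a calcium-binding protein of neutrophils, was at -0.53. Ccr7 was at -0.59, Siglech at -0.25, Car2 at -0.12, Prf1 at 0.03, Lck at -0.05 and Cd8b1 at -0.13. Of genes detected in 1 genotype only, 52 were higher in heterozygous cells. These included Batf3, a transcription factor of dendritic cells, at least 2.05-fold, Tmem176a, at least 1.99-fold, Pls3, 1.77-fold, Fuom, 1.62-fold, and the desaturase gene Fads2, 1.60-fold. A further 69 were lower, such as Reln, at least 2.71-fold, Selenop and Gstm1, each at least 1.79-fold, Tbx6, 1.63-fold, and C2cd2, 1.57-fold. Over both comparisons and their differences, 42 of 84 list percentiles lay outside the limits. By chance 4.2 would be expected if the genes of a list varied independently. Genes of a list can vary together between pools or cultures, so more can lie outside without an effect of genotype or prednisolone. Lists share genes and comparisons share arrays, so these percentiles are not independent.

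Prednisolone responses were mostly somewhat smaller in the heterozygous cells where genes were chosen by the mean response of both genotypes. Among 26 genes with a mean response of at least 2-fold, 19 higher and 7 lower, 20 (76.9%, exact 95% confidence interval over genes 56.4% to 91.0%) had the smaller response in heterozygous cells. This share was 60.9% (45.4% to 74.9%) with the submitters' values and 70.8% (48.9% to 87.4%) with the mean of all probes, so both intervals include an even split. The median difference in the direction of the response was -0.28 (interval -0.40 to -0.14), and the mean response in heterozygous cells was 0.870 times that of wild type. The interval of the median also included 0 under these 2 settings. Tsc22d3 differed by -0.40 (bead SE 0.17), Sesn1 by -0.29 (0.22) and Id2 by -0.64 (0.21), whereas Irs2 differed by 0.11 (0.26) and Saa3 by 0.22 (0.15). Over 195 genes with a mean response of at least 1.5-fold, the median difference was -0.21 (interval -0.28 to -0.15), and 144 genes (73.8%) had the smaller response in heterozygous cells. With genes chosen by the heterozygous response alone, the median turned to 0.17 (interval -0.28 to 0.49). With those chosen by the wild-type response alone it was -0.48. Choosing by 1 genotype favours a larger response in that genotype.

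Among glucocorticoid receptor targets 11 of 18 had a less positive or more negative response in heterozygous cells, with a median difference of -0.13 (percentile 1.61). The count and the median disregard the direction of the response, and only 14 of the 18 were higher in both genotypes. The median stayed negative but moved inside the limits under 4 of 7 alternatives, such as the submitters' values (-0.04, percentile 21.7). Cholesterol synthesis genes had a median difference of 0.20 (percentile 99.7), that is, a smaller decrease in heterozygous cells (-0.35 against -0.54 in wild type). The other 10 lists lay within the limits with the main values, but 3 of them lay outside under some alternatives. Antibody-secreting cell genes, at -0.05 (percentile 9.73), were at -0.10 with the submitters' values (percentile 2.43), -0.15 with no filter (percentile 0.35) and -0.10 with the mean of all probes. Glycolysis genes, at 0.11 (percentile 95.7), were at 0.17 with the submitters' values and 0.16 with the mean of all probes (percentile 99.3 in both). Interferon-stimulated genes, at -0.12 (percentile 3.17), were at -0.15 with the mean of all probes (percentile 1.45). Single genes with strongly negative differences were Bet1 (-1.72), a SNARE of vesicle transport, Rinl (-1.25), Ctdspl2 (-1.23), Gas8 (-1.23), 9830002I17Rik (-1.21), Lrrc8a (-1.19), a volume-regulated anion channel subunit, and Zfp414 (-1.18). Genes with strongly positive differences were Cct2 (1.33), a chaperonin subunit, Zfp940 (1.26), Oxnad1 (1.23), Bloc1s3 (1.22), Pwp1 (1.22), Rgs19 (1.20), Slc22a7 (1.19) and Zbtb14 (1.17). Without background correction the differences were nearer 0, such as -0.81 for Bet1, -0.47 for Zfp414 and 0.47 for Oxnad1. These genes are the extremes of 6634, and several lay near the lowest detected signals of 5.74 to 5.83. For example, Ctdspl2 was at 5.95 in wild type untreated and Oxnad1 at 5.82 in heterozygous untreated cells. The bead SE of the Oxnad1 difference was 0.51. Response differences hardly repeated between probes of a gene (r = 0.07). None of these differences could be tested with 1 array per group.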

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

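No test was run for this part. Bet1, a SNARE of vesicle transport, was the 1 gene of 6634 that passed 1.5-fold in opposite directions in the 2 genotypes, at 0.99 in wild-type and -0.73 in heterozygous cells, a response difference of -1.72. It drew attention because the array pairs of the 2 genotypes moved in opposite directions. The difference was not tested, as each group had 1 array. Its bead SE was 0.41, and it was -0.81 without background correction.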

How the results depend on the processing

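The alternatives below were all planned, and none was added after the results were seen. With an offset of 50, the additive model called 205 genes for prednisolone and 211 for genotype, and 93.8% of responding genes had the smaller response in heterozygous cells. With median scaling the model called 101 and 126. Without background correction 6 genes passed 2-fold for prednisolone and 39 passed 1.5-fold for genotype, and the model called 756 and 573. With the submitters' values these were 24, 160, 0 and 0, with detection on at least 1 array 36, 204, 0 and 0, and with no filter 36, 245, 0 and 0. With the mean of all probes the model called 1 and 0. The share of responding genes with the smaller response in heterozygous cells was 81.8% with median scaling and 90.9% without background correction. It was 60.9% with the submitters' values, 68.1% with detection on at least 1 array, 68.6% with no filter and 70.8% with the mean of all probes. A false discovery rate of 0.1 gave 164 and 208, and an intensity trend in the prior 1014 and 774. At 1.5-fold 90 genes passed for prednisolone, and at 2-fold 18 for genotype. Choosing responding genes by the wild-type response gave a median difference of -0.48 and a share of 96.1%, and by the heterozygous response 0.17 and 46.4%, which reversed both. Choosing by a mean response of 1.5-fold kept them, at -0.21 (-0.28 to -0.15) and 73.8% of 195 genes. The cause of the other shifts was not tested.

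The median response difference was negative under the 7 alternatives of signal, filter and probe, from -0.30 to -0.22, but its interval included 0 with the submitters' values (-0.37 to 0.16) and the mean of all probes (-0.34 to 0.04). The median response of glucocorticoid receptor targets stayed positive under these 7, from 0.27 to 0.46. Of the list medians under all alternatives 227 kept their side of the limits, 8 moved outside and 10 moved inside. Values of named genes stayed within the limits of their bead error 260 times, moved beyond them 56 times and reversed 0 times. No paired analysis was possible because each group had 1 array and no replicate numbers to pair. The additive model compares treatments within genotypes, with genotype as a term, and without any 1 array it would have no residual degree of freedom. Signal over background limits genes such as Nr3c1, which was not above background.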

Other observations

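The tests for an array apart from the others and for fewer macrophages were chosen after the results were seen, and so were the genes in the next 3 sentences. Some genes outside the fixed lists were lower with prednisolone and higher in heterozygous cells, none of them called by the additive limma model. Trib3, a pseudokinase induced by amino acid shortage, was at -1.13 with prednisolone and 1.04 for genotype, and the amino acid transporter gene Slc1a4 at -0.90 and 0.78. The fatty acid elongase gene Elovl6 was at -0.78 and 0.75.

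Genotype and prednisolone differences opposed each other across genes (r = -0.36, Spearman -0.36, over 6634 genes). Of 56 genes lower in heterozygous cells in both treatments 45 had a positive mean response, and 38 of 49 higher genes had a negative one. In 10 of 12 lists the medians had opposite signs. Noise shared within a probe is argued against, since r was -0.35 (-0.39 and -0.32) between different probes of 1537 genes. A single deviating array would tie the genotype difference to the response difference, but that r was 0.0835. Deviations of 2 arrays together may give this pattern and stay open. A lower glucocorticoid signal in untreated heterozygous cells alone would leave a smaller deficit of receptor targets with prednisolone, if the drug brought both genotypes to the same signal. Their median genotype difference was -0.30 untreated and -0.32 with prednisolone, so no smaller deficit was seen. This cannot decide the question, because the prednisolone concentration is not given and each group had 1 array. Single responders went both ways untreated, such as Irs2 at -1.14, Tsc22d3 at -0.11 and Id2 at 0.62. A lower signal in both treatments is a hypothesis that was not tested and also stays open.

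Whether the smaller response in heterozygous cells rests on the choice of genes stays open. Choosing by the heterozygous response gave a median difference of 0.17 (interval -0.28 to 0.49), but that choice raises the difference with or without a true one, and choosing by the mean response gave -0.28 and -0.21. Quantile normalization as the cause is argued against, as median scaling kept -0.24 (-0.34 to -0.08) over the same genes. Unequal noise stays open, because the correlation of the mean response of one probe with the response difference of another was -0.13 (-0.17 and -0.10), too near the limit set of -0.1. The response difference itself hardly repeated between probes of a gene (r = 0.07), whereas the mean response (r = 0.59) and the mean genotype difference (r = 0.63) did.

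For the genotype differences, fewer macrophages in the heterozygous cultures and lower expression per cell cannot be told apart. Only 3 macrophage markers were detected on all arrays, and these 3 were lower in both treatments (Lyz2 at 8.61 against 9.72 untreated), but these decreases were partly known when the test was chosen, B cells also express Ctss, and the labels name no sort. A genomic segment carried along with the targeted allele was not excluded, with 7.53% (exact 95% interval 3.08% to 14.9%) of 93 such genes on chromosome 11, against 8.94% of all genes (one-sided exact Fisher p = 0.738). Within 20 Mb of Ikzf1, 2 of 67 genes differed, against 93 of 5639 overall. A difference between the pools of mice apart from genotype also stays open, because no group had a replicate. Xist was at -0.33 on average (-0.08 untreated, -0.58 with prednisolone) and the Y-linked Ddx3y at -0.28 and -0.78. Unequal sexes of the pooled mice would give opposite directions, which these genes did not show. The question stays open, because Ddx3y with prednisolone passed the 1.5-fold that was set as the limit for no difference.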
